A study of Arabidopsis thaliana with 16 samples.

How the data were processed

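RNA of Arabidopsis thaliana, ecotype Wassilevskija, was measured on an expression array in 16 samples, 8 from the wild type (WT) and 8 from the ppi2 mutant, per the labels. The labels number the samples 1 to 8 in each group and name no tissue, age, growth condition or batch. They do not say which samples came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

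The authors' deposited table held 1 intensity value per probe and sample, for 3439 probes. How the spots were quantified, corrected for background or scaled was not given in the sources used here. From the values, the intensities were on a linear scale, were never negative, and reached a ceiling of 100 in every sample, with 1 to 4 probes at that ceiling. Exact zeros made up 13.0% to 16.6% of the probes of a sample, and whether such a zero was a spot below background or a failed estimate is not known. 99 probes were listed at 0 in all 16 samples and 2375 in none. The 16 columns were matched to samples by their labels, and no column was left unmapped. Arrays carry no read depth, so the number of arrays and the dim end of the scale limited the precision.

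Probe names came from an older platform annotation. It gave 1 gene for 692 probes, several genes for 870, and did not list 1877. No gene was named from a probe with several. The named probes covered 691 genes, and 690 of the probes matched the RefSeq gene table of the assembly TAIR10.1, which was used only for names. The array's own build is not given in the sources used here, so no coordinates are printed. AT2G25870 was the gene with 2 probes, which differed in direction, and it was counted by the brighter of them.

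The following choices were made before the data were examined. Values were to be quantile-normalized between samples if the sample medians spanned more than 0.2 on the log2 scale. Taken over the probes with an intensity above 0 in a sample, the medians spanned 1.70. Values at or under the 5th percentile of positive normalized intensities, 0.0338 or -4.89 on the log2 scale, were set to that floor before log2 was taken. 244 probes were at or under the floor in every sample. Consecutively numbered samples were to be averaged if each sample correlated best with its partner. All 8 WT and all 8 ppi2 samples did, with Pearson's r across probes of 0.902 to 0.938 within WT pairs and 0.959 to 0.979 within ppi2 pairs, against at most 0.870 and 0.953 for other combinations in the same group. Each such pair was therefore counted as 1 replicate (n = 4 per group). The labels do not say what these pairs are.

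Differences, always ppi2 minus WT, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend), with Benjamini-Hochberg adjustment over all 3439 probes and a threshold of 0.05. The fit had 6 residual degrees of freedom and a prior of 0.677, so the spread of each probe was little moderated. A fold against a group with every sample at the floor is given as a lower bound, taken against the floor. 20 gene lists with 346 genes were fixed by locus: light-harvesting proteins, photosystem subunits, electron carriers and ATP synthase, the Calvin cycle, chlorophyll synthesis, carotenoids, protein import, thylakoid targeting, plastid ribosomal proteins, chaperones and proteases, antioxidants, starch and envelope transport, nitrogen assimilation, plastid lipids, plastid transcription and division, photorespiration, jasmonate, phenylpropanoids, isoforms of roots and non-green plastids, and cytosolic housekeeping genes. Only 16 of these genes had a probe of their own. Lists with at least 3 measured members were tested against the other named genes with camera, with a preset correlation of 0.01 and with an estimated correlation. Fry tested the same lists against no change, without reference to other genes.

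The rule for named genes took the gene that ppi2 disrupts, import genes past the threshold, the 8 largest increases and 8 largest decreases that passed the test with a brighter-group mean above the median of all probes and every ppi2 pair on the same side of the WT mean, and the 2 members with the smallest p from each list with 3 or more measured. For probes without a listed gene it took at most 2 in each direction. The other measured list members are named beyond that rule, since so few were measured.

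The procedure was tested on simulated data with the spread of 3195 probes, 200 of them changed, in 5 simulations of 4 against 4. It recovered 27.2% of changes of 1 on the log2 scale, 68.7% of changes of 2 and 90.5% of changes of 3. Of the calls, 4.52% were false, and 0 changed probes were called with the wrong sign. The simulated values were independent normal draws, with 1 SD per probe for both genotypes and no floor. In the data the median SD over pairs was 0.662 in WT and 0.291 in ppi2. The WT pairs also fell into subsets, and many values were at the floor. These rates may therefore not hold for the data. Alternatives covered the scaling between samples, the floor, the filter on dim probes, the treatment of zeros and of the sample pairs, the replicate number as a block, each replicate left out in turn, the moderation of the test and the kind of list test. The plots were drawn with matplotlib 3.10.9.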

Results

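The series compared RNA of the ppi2 mutant of Arabidopsis with that of its wild type. The ppi2 mutant lacks Toc159, a receptor of the translocon in the outer envelope of chloroplasts, and is known for albino seedlings. The question was which transcripts differ when the import of precursor proteins into chloroplasts is impaired. There were 16 samples, 8 per genotype, which formed 4 averaged pairs per genotype (n = 4 per group in everything that follows). The median deposited intensity of a sample lay between 0.0976 and 0.213 in WT and between 0.168 and 0.269 in ppi2, on a scale that ended at 100. Toc159 itself was not named by any probe with a listed gene of its own, nor was any other gene of the import list, so the target gene gave no check of the labels.

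Transcripts of photosynthesis differed between the genotypes in both directions. LHCB1.5 (AT2G34420), a chlorophyll-binding protein of the light-harvesting antenna, fell 9.11-fold in ppi2, from a normalized intensity of 16.9 to 1.86 (log2 fold change -3.19 ± 0.25 SE, limma with Benjamini-Hochberg adjusted p = 0.000311). PSAN (AT5G64040), a subunit on the lumenal side of photosystem I, fell 6.46-fold (-2.69 ± 0.49, adjusted p = 0.00858). PSBW (AT2G30570), a small subunit of photosystem II, rose 5.64-fold, from 14.3 to 80.6 (2.50 ± 0.43, adjusted p = 0.00717). PRK (AT1G32060), the phosphoribulokinase of the Calvin cycle, fell 3.94-fold (-1.98 ± 0.37, adjusted p = 0.00935). In each of these genes the 4 ppi2 pairs lay outside the range of the 4 WT pairs. That was so in 31.7% of the 691 genes with a probe of their own, and 28.1% of the 691 passed the test. LHCB1.5, PSAN, PSBW and PRK were each measured by 1 probe. PSBW stood lower in WT pair 1, at a log2 level of 2.50, than in the other WT pairs, at 4.13 to 4.37. In the values as deposited PSAN fell 4.28-fold and PRK 2.35-fold, and after centring on the sample medians PSBW rose 3.58-fold.

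Among the 3 measured photosystem subunits, 1 rose, 1 fell and PSBY (AT1G67740) did not pass the test (0.17 ± 0.41, 95% interval -0.80 to 1.14). Adjusted over the list alone, 2 of the 3 passed. The median log2 change of this list was 0.17 and its mean -0.01, so these differed in sign. Camera found no shift against the other named genes (adjusted p = 0.918, and adjusted p = 0.933 with an estimated correlation), and fry gave an adjusted p = 0.735 for a common direction and an adjusted p = 0.0269 for change in either direction, all from limma. The direction that camera assigned to this list turned under several alternatives, as did the sign of PSBY. The single measured antenna protein was LHCB1.5. Of the 2 measured Calvin cycle genes 1 fell, PRK, while SBPASE (AT3G55800) was listed at 0 in all 16 samples.

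Of the 6 measured plastid ribosomal protein genes 0 rose, 1 fell and 5 did not pass the test, and adjusted over the list alone 1 passed. The gene that fell was AT1G29070, which encodes plastid ribosomal protein L34, at 3.93-fold lower (-1.97 ± 0.41, limma adjusted p = 0.0132). AT5G65220 (L29) was 1.69 ± 0.79 higher on the log2 scale (limma adjusted p = 0.162), a value that rested on WT pairs 3 and 4, against which it was 8.54-fold higher, compared with 1.22-fold against WT pairs 1 and 2. The log2 differences of the others were -0.60 ± 0.31 for AT3G54210 (L17), -0.25 ± 0.41 for AT3G13120 (S10) and -0.16 ± 0.36 for AT4G01310 (L5). AT1G64510 (S6) was at the floor in all ppi2 pairs and was listed at 0 in 6 of the 8 WT samples. Camera gave this list a downward direction with adjusted p = 0.582 (adjusted p = 0.641 with an estimated correlation). Fry in limma gave an adjusted p = 0.0498 for a common direction and an adjusted p = 0.0269 for change in either direction. The fall of AT1G29070 was 1.91-fold and did not pass with a floor at the 25th percentile of intensities (limma adjusted p = 0.086), and it was 6.25-fold with zeros set to missing. Some of the others passed under other settings: AT4G01310 was 0.79 higher in the values as deposited (limma adjusted p = 0.017) but differed by -0.80 against WT pairs 3 and 4 alone (0.007), where AT5G65220 (0.000525) and AT1G64510 (0.00467) passed too. AT5G65220 also passed without WT pair 2 (limma adjusted p = 0.0428), with the sample pairs as a random block (0.0236) and with every sample as its own replicate (0.0169), and AT3G54210 passed without WT pair 1 (0.0302).

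In chlorophyll synthesis, AT1G74470, the geranylgeranyl reductase that makes the phytol tail of chlorophyll, rose 1.79-fold (0.84 ± 0.19, limma adjusted p = 0.0165). CHLM (AT4G25080), the methyltransferase of magnesium-protoporphyrin, differed by -0.26 ± 0.21 (limma adjusted p = 0.408). AT1G74470 stayed higher but did not pass the test in the values as deposited (1.38 on the log2 scale, limma adjusted p = 0.0689), after centring on the sample medians (0.80, 0.0673), or against WT pairs 1 and 2 alone (0.69, 0.103). FATB (AT1G08510), a thioesterase that releases fatty acids from their carrier in plastids, rose (1.72 ± 0.23, limma adjusted p = 0.00231) from a WT level at the floor in 3 of 4 pairs. The size of its rise, 3.30-fold, was set by the floor, with 1.13-fold for a floor at the 25th percentile of intensities and 8.63-fold at the 1st, and 5.52-fold with zeros set to missing. The plastid peroxiredoxin AT3G52960 differed by -1.04 ± 0.41 (limma adjusted p = 0.109), and it passed when adjusted over its list alone, of which it was the only measured member. AT3G52960 also passed after centring on the sample medians (limma adjusted p = 0.0157), with every sample as its own replicate (0.0148) and without WT pair 4 (0.0297). The other 13 lists had no measured member, including the import machinery, the isoforms of roots and non-green plastids that would mark other tissue, and the housekeeping genes.

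**Figure D1:**
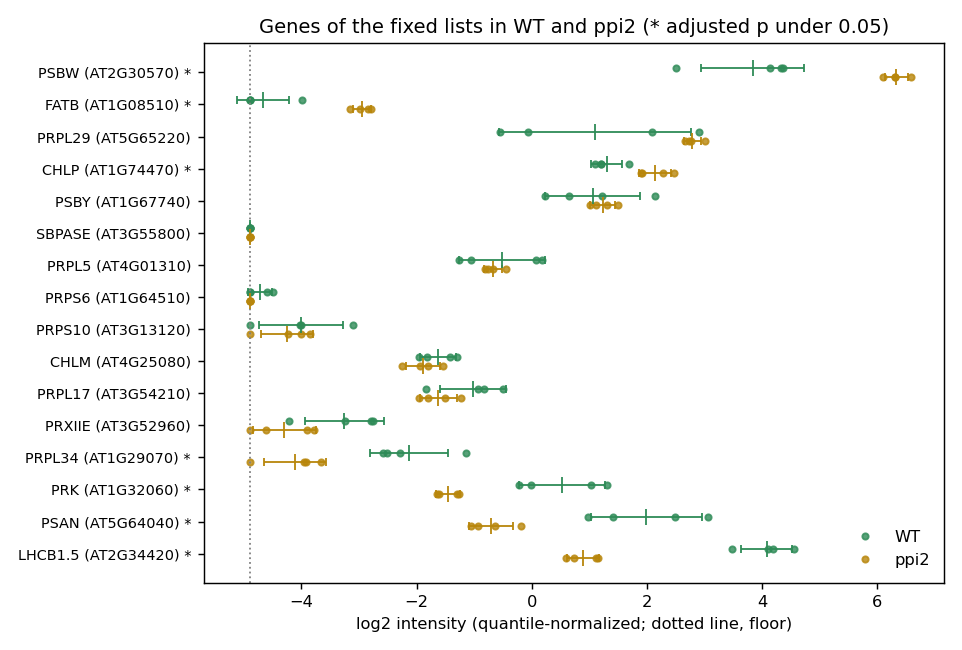
Normalized log2 intensity of the 16 measured genes of the fixed lists in WT and ppi2, with 1 point per averaged pair and bars for the mean ± SD (n = 4 per group). The dotted line is the floor at -4.89, and asterisks mark genes with a limma adjusted p under 0.05. LHCB1.5, PSAN and PRK lay lower and PSBW lay higher in every ppi2 pair than in any WT pair.

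Beyond these lists, the largest increase of a named gene was that of AT1G76450, a PsbP-domain protein, at 47.3-fold (5.56 ± 0.97, limma adjusted p = 0.00724). AT4G18180 rose 42.1-fold (5.40 ± 1.44, limma adjusted p = 0.0321). AT1G06510 rose 23.8-fold, AT5G49840, which encodes a ClpX-type subunit of the Clp protease, 20.2-fold, and AT1G05490, listed as the chromatin remodeling gene chr31, 20.1-fold. WT pairs 3 and 4 of AT1G06510 and 3 of the 4 WT pairs of AT1G05490 were at the floor, so these folds moved with it. With floors at the 25th and the 1st percentile of intensities they were 9.88-fold and 46.6-fold for AT1G06510, 6.88-fold and 55.4-fold for AT1G05490, 13.1-fold and 21.5-fold for AT5G49840, and 22.8-fold and 70.1-fold for AT4G18180. After cyclic loess the rises of AT4G18180, AT1G06510, AT5G49840 and AT1G13370 were 25.3-fold, 15.2-fold, 12.2-fold and 11.4-fold. With zeros set to missing the log2 fold change of AT4G18180 was 4.52, and AT1G05490 rose 34.1-fold then and 32.9-fold in the values as deposited. The histone H3 family gene AT1G13370 rose 18.4-fold and the protein kinase gene AT5G40030 rose 17.9-fold. AT2G46220 rose 17.1-fold from a clear WT signal, from 2.29 to 39.2 (limma adjusted p = 9.36e-05). The sizes at the top depended on the WT pairs. Against WT pairs 1 and 2 and against WT pairs 3 and 4 they were 14.2-fold and 158-fold for AT1G76450, 6.85-fold and 258-fold for AT4G18180, 10.6-fold and 38.6-fold for AT5G49840, and 9.72-fold and 34.8-fold for AT1G13370. For AT4G18180 the 258-fold was set by the floor, which it met or nearly met in WT pairs 3 and 4 (log2 levels of -4.89 and -4.77). AT1G76450 was 72.4-fold higher without WT pair 1 and 29.0-fold without WT pair 4. AT4G18180 was 77.9-fold higher without WT pair 1, 76.3-fold without pair 2, 22.7-fold without pair 3 and 23.3-fold without pair 4. Its limma adjusted p rose to 0.067 and 0.0629 without WT pairs 3 and 4 respectively, and lay between 0.0735 and 0.0808 when any ppi2 pair was left out, so its call was lost in these fits.

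The largest decrease was that of GH9B12 (AT2G44570), an endoglucanase of glycosyl hydrolase family 9B, at 26.1-fold lower (-4.71 ± 0.40, limma adjusted p = 0.000457). LHCB1.5 came next. AT3G06570 fell 8.95-fold (-3.16 ± 0.18, limma adjusted p = 0.000111), AT3G25840 8.38-fold, AT5G38360 8.11-fold and AT5G53920 7.99-fold. PRA1.B6 (AT5G07110), a prenylated RAB acceptor, fell 7.59-fold. AT2G35490, a plastid fibrillin, fell 6.81-fold (-2.77 ± 0.37, limma adjusted p = 0.00238). With a floor at the 25th percentile of intensities GH9B12 fell 11.8-fold and AT3G25840 fell 4.69-fold. In the values as deposited AT3G25840 fell 4.86-fold, AT5G53920 4.77-fold and AT2G35490 3.97-fold. The call of each of these genes held in all 23 alternatives that gave it a value.

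Among probes without a listed gene, probe 909 had an intensity of 3.67 in WT and was at the floor in every ppi2 sample, which made it at least 109-fold lower in ppi2 (limma adjusted p = 1.98e-07). Probe 3199 fell 42.8-fold (-5.42 ± 0.33), with ppi2 pairs 1 and 2 at the floor. Probe 4585 rose 49.0-fold (5.61 ± 0.89) and probe 749 rose 30.8-fold (4.94 ± 0.74). Probe 4585 was 75.5-fold higher without WT pair 1 and 30.8-fold without WT pair 3, and the log2 fold change of probe 749 was 4.32 without WT pair 4. With floors at the 25th and the 1st percentile of intensities, probe 909 was at least 30.7-fold and 473-fold lower, probe 3199 was 15.1-fold and 140-fold lower, and probe 4585 was 30.1-fold and 72.7-fold higher. The log2 fold change of probe 4585 was 6.41 with zeros set to missing and 4.79 after cyclic loess, where that of probe 909 was -7.72. Against WT pairs 1 and 2 and against WT pairs 3 and 4, probe 4585 was 16.4-fold and 146-fold higher and probe 749 was 13.5-fold and 70.4-fold higher. WT pair 3 of probe 4585 was at the floor, so its 146-fold moves with the floor.

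**Figure D2:**
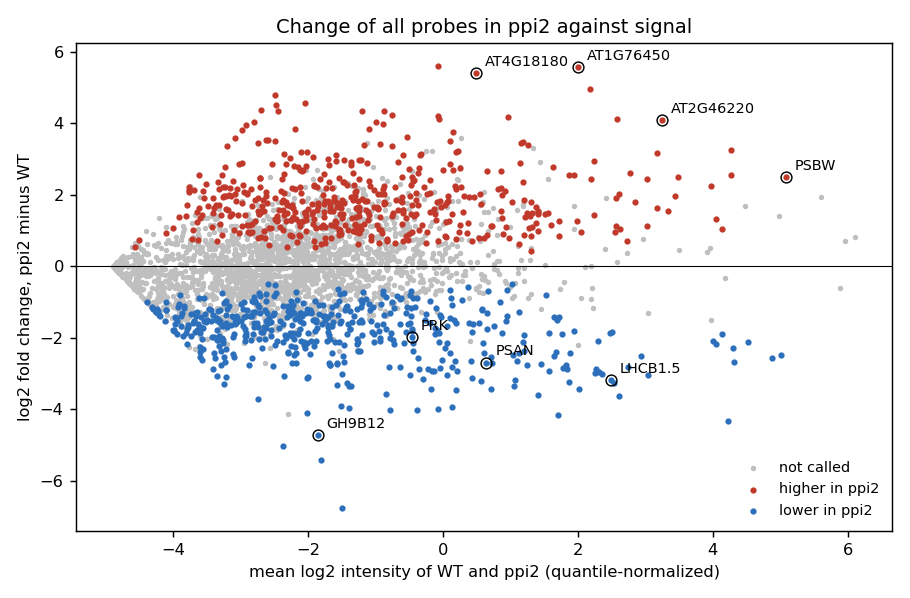
Log2 fold change (ppi2 minus WT) of 3439 probes against their mean normalized log2 intensity, with 488 probes called higher in red and 496 called lower in blue (limma adjusted p under 0.05, n = 4 averaged pairs per group). Circles mark genes named in the text. Called probes lay on both sides of 0 among dim and bright probes, and the slanted left edge is where the dimmer group sat at the floor.

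In total, 984 of 3439 probes (28.6%) differed between ppi2 and WT by limma, 488 of them higher and 496 lower in ppi2. Of these, 416 rose and 445 fell by more than 2-fold, and 52 rose and 43 fell by more than 8-fold. For the 691 genes with a probe of their own, 110 rose and 84 fell (28.1%). The 1877 probes without a listed gene gave 263 rises and 293 falls, and the 870 probes with several genes 115 and 119. In 9 of the called increases all WT samples were at the floor, and in 19 of the called decreases all ppi2 samples were. The groups did not overlap at all in 1106 probes (32.2%), where chance gives 2.86%. Quantile normalization makes the distributions of all samples equal, so a shift of most transcripts could not be seen with it. In the values as deposited the median of all probes was 0.30 higher in ppi2 on the log2 scale. There 647 probes rose while 235 fell, a share of 73.4% higher in place of 49.6%. Only WT pairs 3 and 4, with sample medians of 0.0976 to 0.124, lay below the 0.168 to 0.269 of ppi2. WT pairs 1 and 2, at 0.198 to 0.213, lay within that range. The shift is therefore no evidence that most transcripts rose in ppi2.

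The WT samples varied more than the ppi2 samples. The median SD over pairs was 0.662 in WT and 0.291 in ppi2 on the log2 scale. Across probes, which are not independent replicates, the ppi2 pairs correlated with each other at 0.943 to 0.961. WT pairs 1 and 2 correlated at 0.898 and WT pairs 3 and 4 at 0.885, but pairs of the first kind with pairs of the second only at 0.759 to 0.812. WT pairs 1 and 2 correlated with the ppi2 pairs at 0.761 to 0.806, about as closely as with the other WT pairs, and WT pairs 3 and 4 at 0.625 to 0.667. The labels give no batch that would account for this split within WT. WT pairs 3 and 4 were also the dimmest of all samples as deposited, with medians of 0.0976 to 0.124. WT pairs 1 and 2, at 0.198 to 0.213, lay within the range of ppi2, 0.168 to 0.269. Every sample reached the same ceiling of 100, so these medians may be relative to the brightest spots and need not reflect signal strength. Whether signal strength and the split are tied was not tested, apart from a comparison of ranks given below. That comparison covers only differences that keep the order of probes. In fits added after the split was seen, 1003 probes differed against WT pairs 1 and 2 alone and 1452 against WT pairs 3 and 4 alone. LHCB1.5 was 7.44-fold lower against WT pairs 1 and 2 and 11.2-fold lower against WT pairs 3 and 4, PSAN 3.73-fold and 11.2-fold, and PRK 2.53-fold and 6.14-fold. PSBW was 7.44-fold and 4.28-fold higher.

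**Figure D3:**
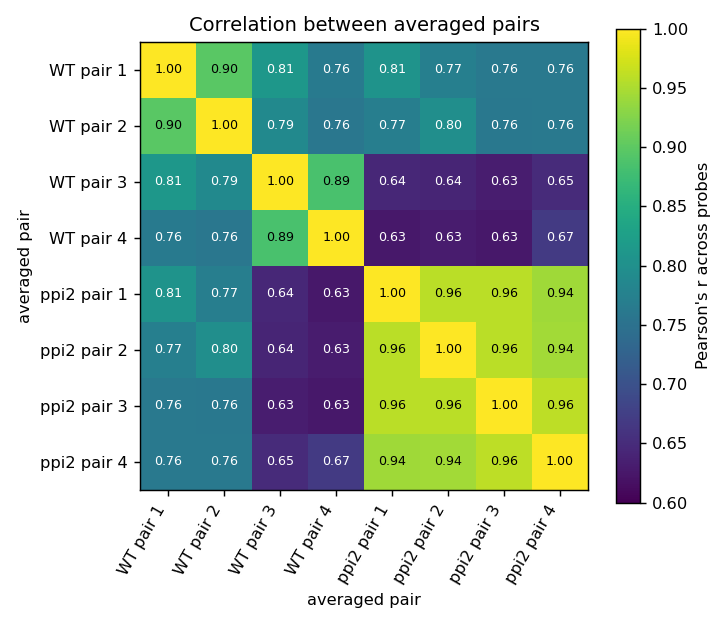
Pearson's r across 3439 probes between the 8 averaged pairs, 4 of WT and 4 of ppi2, on normalized log2 intensities. The ppi2 pairs form a block at 0.943 to 0.961, while WT pairs 1 and 2 (0.898) stand apart from WT pairs 3 and 4 (0.885).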

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

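The rank comparison within WT was chosen only after its result was seen, and the mixing test was set before its result but after the split within WT had been noticed.

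Among the named genes, 4 averaged pairs stood far from the other 3 of their group, all of them WT pairs. 68 groups of 4 pairs were examined, where a rate of 1 in 20 would give 3.4 such cases. PSBW (AT2G30570) had a log2 level of 2.50 in WT pair 1, against 4.13 to 4.37 in the other WT pairs. AT3G25840 was at -0.21 in WT pair 3, against -1.10 to -0.95. AT1G05490 was at -3.79 in WT pair 4 and FATB (AT1G08510) at -3.995 in WT pair 2, where the other WT pairs were at the floor of -4.89 in both genes. With the others tied at the floor, any value above it is flagged. The rate of 1 in 20 does not hold for such groups.

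WT pairs 1 and 2 stood apart from WT pairs 3 and 4: AT1G76450 was 14.2-fold higher in ppi2 against the former and 158-fold against the latter, and AT4G18180 was 6.85-fold higher against WT pairs 1 and 2 and at or near the floor in WT pairs 3 and 4 (log2 levels of -4.89 and -4.77). Of the other top increases, AT5G49840, AT1G13370 and AT5G40030 were also larger against WT pairs 3 and 4 (26.2-fold to 38.6-fold, against 9.72-fold to 12.2-fold). So was AT1G06510 (16.2-fold and, with WT pairs 3 and 4 at the floor, at least 35.0-fold). AT2G46220 was not (17.3-fold and 16.9-fold). AT1G05490 ran the other way, at least 24.4-fold higher against WT pairs 1 and 2 and 16.7-fold against WT pairs 3 and 4. With WT pairs 1, 2 and 3 at the floor, it could not show a larger rise against WT pairs 3 and 4. Over 2375 probes above 0 in every sample, Spearman's rho was 0.776 to 0.820 within the WT subsets and 0.584 to 0.675 across them. The difference of medians, 0.193, argues against an order-keeping difference in exposure or scaling as the cause of the split within WT. It adds little to the correlations of normalized values, since quantile normalization already removes most of such a difference. Mutant RNA mixed into WT pairs 1 and 2 at a small share may account for part of the split and stays open. In WT pairs 1 and 2, 45 probes bright in ppi2 and dim in WT pairs 3 and 4 had a median of 25.7% of their ppi2 level (5th to 95th percentile 5.93% to 97.9%). Of these probes 5, or 11.1% (exact binomial interval 3.71% to 24.1%), lay below 0.25 of that median. Mixing would give every such probe at least the mixed share of its ppi2 level. These 5 probes thus argue against a mixed share near 25.7%, but not against a smaller one. The bound against mixing, 10%, was set before the share was computed, while the requirement that the interval clear it was added afterwards, and a difference in growth, age or harvest between the WT samples was not tested, because the labels give none.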

How the results depend on the processing

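The fits on subsets of WT, the floors at the 1st and 25th percentiles, the fit without probes at the floor throughout and the list test against all probes were chosen only after the data were seen. The number of probes that differed, 984 here, lay between 819 and 1240 in the alternatives apart from those named next. Quantile normalization was listed as an alternative and is the scaling used. With every sample as its own replicate 1616 probes differed, 787 higher and 829 lower, and 333 named genes, because the sample pairs then count double. Against WT pairs 3 and 4 alone 1452 probes and 293 named genes differed, and the cause was not tested. In the values as deposited 235 probes were lower and 73.4% of the changed probes were higher, where the median of all probes shifted by 0.30. After centring on the sample median that shift was -0.28. Leaving out each averaged pair in turn gave 686 (without ppi2 pair 3) to 1087 (without WT pair 2) probes and 137 to 221 named genes. Of the 26 named genes and probes that passed, none changed sign in any of 23 settings. AT4G18180 lost its call in 7 settings, AT1G74470 in 3 and AT1G29070 in 1.

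With the replicate number as a block 846 probes differed, 750 of them shared, and among named genes and probes only AT4G18180 lost its call (adjusted p = 0.0616). The numbers were not taken to pair the samples, which rests on pair 3: deviations of same-numbered pairs correlated at 0.381, 0.307, 0.0313 and 0.330, pairs 1, 2 and 4 matched each other best, and WT pair 3 matched ppi2 pair 4 best while ppi2 pair 3 matched WT pair 3.

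Camera turned the photosystem list downward, never past the threshold, in the values as deposited (adjusted p = 0.742), after median centring (0.999), cyclic loess (0.903) and the filter on dim probes (0.934), against WT pairs 3 and 4 (0.952) and without WT pair 2 (0.961) or 4 (0.970), where leaving out each pair gave 0.609 to 0.970. The ribosomal list passed only with fry (adjusted p = 0.0498), which asks another question. Genes below the threshold that turned were, in log2 units, AT4G25080 (0.55), AT4G01310 (0.79), AT3G54210 (0.24) and AT3G13120 (0.031) as deposited, AT4G01310 (0.22) after centring, and AT1G64510 (0.047) and AT3G13120 (0.0745) with loess. Leaving out each pair gave -0.54 to 0.053 for AT3G13120, above 0 without WT pair 1, -0.11 to 0.53 for AT1G67740, below 0 without WT pair 2, and -0.41 to 0.075 for AT4G01310, above 0 without WT pair 3 or 4. Against WT pairs 1 and 2, AT4G25080 (0.0068) and AT4G01310 (0.48) turned, and against WT pairs 3 and 4 AT1G67740 (-0.17). The cause was not tested. Signal limits the dim end, with 244 probes at or under the floor in every sample.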

Other observations

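The gene groups described here and the tests of other splits, of scaling, of adjusted p within the parts of WT and of second probes were chosen only after the values were seen.

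Some factors that assemble the photosynthetic complexes passed the test. LPA19 (AT1G05385), an assembly factor of photosystem II, fell 6.42-fold (-2.68 ± 0.48, limma adjusted p = 0.00758), and SECE1 (AT4G14870), a subunit of the Sec translocase in the thylakoid, fell 3.08-fold (-1.63 ± 0.18, limma adjusted p = 0.00117). AT1G22700, known as PYG7, which is needed for photosystem I to accumulate, rose 6.34-fold (2.67 ± 0.35, limma adjusted p = 0.00227). Of the 6 measured genes of this group 1 rose, 2 fell and the other 3 did not pass, with limma's fry giving an adjusted p = 1.22e-05 for change in either direction and camera an adjusted p of 0.456 for a shift (0.496 with an estimated correlation). In the group around the chloroplast NDH complex, an electron carrier complex next to photosystem I, 2 of 7 genes rose and 2 fell, while the other 3 (NdhN, CRR41 and OTP85) were at or near the floor in both genotypes, where a fall could not be seen. The subunit NdhS (AT4G23890) rose 3.90-fold (1.96 ± 0.44, limma adjusted p = 0.0170, but 0.0618 in the values as deposited) and the RNA editing factor CRR21 (AT5G55740) rose 2.44-fold (limma adjusted p = 0.0455). PIFI (AT3G15840) fell 2.94-fold and the chaperonin subunit Cpn60beta4 (AT1G26230) fell 3.27-fold. Cpn60beta4 had a log2 level of -4.07 in ppi2, near the floor of -4.89, so its fold may move with the floor. Fry in limma gave an adjusted p = 1.87e-05 for change in either direction and camera an adjusted p of 0.866.

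Of 4 measured redox genes 2 rose. The thioredoxin reductase NTRC (AT2G41680) rose 2.94-fold (limma adjusted p = 0.0136). CCS (AT1G12520), the copper chaperone of superoxide dismutase, rose 3.93-fold (limma adjusted p = 0.00318). Its log2 level went from -4.14, near the floor of -4.89, to -2.17, so this fold may move with the floor. SRX (AT1G31170) and CHL (AT3G47860) did not pass, and SRX was at the floor in every ppi2 sample. Camera gave the redox group an adjusted p of 0.456 and fry an adjusted p = 0.00235 for change in either direction. Among 4 endoglucanases of family 9B only GH9B12 passed the test. Its close relative GH9B11 (AT2G44560) was -0.89 ± 0.37 on the log2 scale (limma adjusted p = 0.120), and the group had a camera adjusted p of 0.456 and a fry adjusted p of 0.00595 for change in either direction. These groups were drawn up from genes whose values had been seen, so their p-values describe them and are no independent evidence.

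If the 8 averaged pairs can be exchanged freely, a chance division of them is argued against as the source of the number of calls. Of the 35 splits of the 8 averaged pairs into 4 and 4, only 1, the real one, gave as many as 984 calls by limma. The highest count of any other split was 0. At an unadjusted p under 0.05 the real split gave 1393 probes and the highest other split 338. The smallest share that 35 splits can give is 1 in 35. Every other split mixes the genotypes, so its spread holds the difference between them. Same-numbered pairs 1, 2 and 4 matched each other best across genotypes. The WT pairs also fell into subsets, and the median SD over pairs was 0.662 in WT and 0.291 in ppi2. Free exchange is therefore doubtful. Swaps within same-numbered pairs alone would be too few for a share under 0.05.

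PSBW and NdhS rose while LHCB1.5, PSAN and PRK fell, and technical explanations of this opposition were weighed. For scaling between samples, the signs of all 5 log2 fold changes, with nothing subtracted, were compared. They held in the values as deposited and after quantile normalization, median centring and cyclic loess. As deposited NdhS rose by 2.15 ± 0.69, but did not pass the threshold (limma adjusted p = 0.0618). The choice among these scalings thus did not make the opposition. It is no test of scaling as such, since the genes were chosen after their values were seen. Their changes were also larger than the shifts of the median of all probes, 0.30 as deposited and -0.28 after centring, so a sign could hardly turn. That all 5 signs held against WT pairs 1 and 2 and against WT pairs 3 and 4 decides nothing, since the genotypes did not overlap in these genes. All 5 genes also passed the test within each part of WT. Their limma adjusted p was at most 0.0417 against WT pairs 1 and 2 and at most 0.00484 against WT pairs 3 and 4. In these genes the difference thus did not rest on 1 part of WT alone. This is no independent evidence, since the genes were chosen from these data and both fits used the same ppi2 pairs. Of the 26 named genes and probes that passed, 25 kept their call against WT pairs 1 and 2 and 26 against WT pairs 3 and 4. Probes that catch the RNA of a related gene, or that carry an outdated gene name, stay open as a possible explanation, because 0 of the 5 genes had a second probe of their own. The 2 probes of AT2G25870, the only gene with more than 1, gave log2 fold changes of 1.05 ± 0.13 (limma adjusted p = 0.00185) and -0.64 ± 0.28 (0.142). A difference between genes in how their transcripts respond to impaired import may be at work, but it cannot be told apart from misassigned probes here.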
